A study of Mus musculus with 4 samples.

How the data were processed

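The series measured RNA in the brains of 4 male C57BL/6 mice aged 8 to 9 weeks, 2 wild-type and 2 Bcas1 knockout, obtained per the labels by breeding heterozygous animals. The title and protocols name the brain, and the sample descriptions name the cerebrum. Per the labels' protocols, total RNA was treated with DNase, and biotin-labelled amplified RNA was made from 100 ng with a GeneChip 3' IVT Express kit and hybridised to 1-colour Affymetrix arrays, 1 array per mouse. This chemistry primes at the 3' end of transcripts, so most probe sets read the end of a gene.

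The deposited table holds 1 log2 level per probe set and array, which the authors computed with RMA, per the submitters' processing notes. RMA corrects the background, normalizes the probes between arrays to a common distribution and summarises the probes of a set by a robust fit. The software, its version and its settings are not given in the sources used here. The values were rounded to 2 decimals in the table, which left 75 probe sets with no spread within either group. No detection calls accompanied the values, so a dim level could not be separated from background, and a fold change of a dim gene is compressed. Scanner files were not used here, so background correction and summarisation were not repeated. No depth applies to arrays, and the number of arrays limits the precision.

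The table has 45101 rows. The 64 Affymetrix control probe sets were left out of the tests and 45037 were tested. Genes were named from the platform annotation table supplied with the series. In it 34945 probe sets named 1 gene, 932 named several genes and were given no single gene name, and 9160 were unnamed here. Symbols were looked up by Entrez number in the RefSeq gene table of assembly GRCm38.p6, which changed 0 of them. That table also supplied chromosomes and gene order, and no coordinates are given because the array values carry no genome build. Each of 18193 genes was represented by its brightest probe set over all 4 arrays, and 9010 of the genes had more than 1 probe set.

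Knockout was compared with wild type in limma 3.58.1 (R 4.3.3) by lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The design left 2 residual degrees of freedom per probe set, to which the empirical Bayes step added 2.74 prior degrees of freedom. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333. For that reason the number of probe sets at least 1.5-fold apart, with both knockout arrays on one side of both wild-type arrays, was set beside the same count for the other ways of splitting the arrays. On simulated data with the same levels and fitted spread, covering 45037 probe sets, the test recovered 100% of 50 planted log2 decreases of 3, 98% of those of 2 and 64% of those of 1, and 58% of increases of 1, with 9 false calls. All sizes were planted in the same data, and many true changes at once ease the Benjamini-Hochberg adjustment. These shares therefore do not apply to the real data, where 2 probe sets passed and Bcas1 at -1.29 had an adjusted p of 0.742 in limma.

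Before the data were examined, 24 gene lists of brain cell types, regions and pathways were fixed from general knowledge, as were the rule for named genes and the alternatives. The lists were tested on the representative probe sets with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 24 lists. At this setting camera compares the genes of a list with all other genes, and its p does not measure the spread between mice. On simulated data over 18193 genes, a planted shift of -0.3 in the myelin list was called by camera with an adjusted p of 1.2e-12, and 0 of 23 unshifted lists were called. The simulated genes were drawn independently of each other, while in the data the estimated correlation of called lists reached 0.469 (blood cells). The simulation therefore cannot show how often lists of correlated genes are called falsely. The planted shift was also larger than the median of 0.075 of the mature oligodendrocyte list. The rule for named genes took Bcas1; the 12 highest-ranked genes in each direction with both knockout arrays outside the wild-type range; up to 4 members of each list; and Mbp, Mog, Mag, Gfap and Aif1. The 12 were those past the threshold, filled by smallest p; the level and overlap conditions were also applied to the filled genes, which the rule left open. Genes named outside this rule are marked as chosen after their values were seen. Not every gene taken by the rule is reported here. A further 7 marker lists were written after a first ranking of the probe sets, 6 of them of genes that this ranking had not shown. Of the measured genes in the pituitary, erythroid and neutrophil lists among them, 3, 2 and 3 were also members of the 24 fixed lists.

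The alternatives were median-centred arrays, repeated quantile normalization, a filter on dim probe sets, an intensity trend with robust variance, the replicate number as a block, leaving out each array, averaging the probe sets of a gene, an estimated inter-gene correlation, fry, and a 2-fold threshold. Array weights were added after 1 knockout array was seen to stand apart. No pair of arrays held the same values, and at most 1791 of the 45037 probe sets had equal rounded values in any pair. Titles number the mice 1 and 2 in each group, and nothing in the labels ties equal numbers to a litter or a day. Of the per-sample value columns, 0 were left unused.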

Results

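Brain RNA of 2 wild-type and 2 Bcas1 knockout male mice was profiled on Affymetrix arrays, 1 mouse per array. Bcas1 encodes a protein of myelinating oligodendrocytes, the glial cells that wrap axons in myelin, and the design asks how the brain transcriptome differs when the gene is disrupted. Levels are RMA values on a log2 scale. The arrays had medians of 6.49 to 6.51 and lower quartiles of 4.86 to 4.91. The 3' minus 5' difference of the actin control, a measure of RNA integrity, was 1.09 and 1.12 in wild type and 1.14 and 1.15 in the knockout. Correlations between arrays across probe sets ranged from 0.996 to 0.998, where probe sets are not independent replicates. Each array is described by the labels as a separate mouse, so the SDs give the spread between 2 mice per group. The SEs and p-values of limma use a moderated variance, which draws that spread toward a prior pooled over all probe sets. Cacng4, with SDs of 0 and 0.0071, thus has an SE of 0.068.

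Bcas1 RNA was lower in the knockout but was not absent from the array signal. The brightest Bcas1 probe set measured 12.19 ± 0.028 (SD, n = 2) in wild type and 10.90 ± 0.21 (SD, n = 2) in the knockout. The difference was -1.29 (SE 0.12), a 2.45-fold lower level. It had the adjusted p of 0.742 in limma over all probe sets and so did not pass the threshold. The 2 other Bcas1 probe sets were dim and differed in the opposite direction. They were 0.77 (SE 0.18) and 0.64 (SE 0.15) higher in the knockout, both with an adjusted p of 1 in limma. Where the 3 probe sets lie relative to the disrupted part of the gene is not given in the sources used here, and a probe set outside it would not test the labels. With an intensity trend and robust variance the same difference of the brightest probe set reached an adjusted p of 0.038 in limma, and the other settings tried gave an adjusted p of 0.405 to 1.

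Erdr1 and 1 unnamed probe set were the features that fell in the knockout, and no probe set rose. Erdr1, placed on the X chromosome in the gene table used, fell by 3.01 (SE 0.086), from 10.74 ± 0.11 to 7.73 ± 0.042 (SD, n = 2 each), an 8.03-fold decrease with an adjusted p of 0.015 in limma. The unnamed probe set fell by 3.89 (SE 0.084), from 8.18 ± 0.099 to 4.30 ± 0.035 (SD, n = 2 each), a 14.8-fold decrease with an adjusted p of 0.0079 in limma. The second Erdr1 probe set was dim, with a difference of -0.31 (SE 0.18). In counts, 0 of 45037 probe sets were higher and 2 were lower past the threshold, and by gene 0 were higher and 1 was lower. At an unadjusted p under 0.05, limma gave 818 higher and 724 lower probe sets, 1542 together, where chance alone would give 2252. Leaving out any 1 of the 4 arrays gave 0 calls in both directions, while the Erdr1 difference stayed between -3.08 and -2.93. The adjusted p for Erdr1 in limma was 1 without the first wild-type array, 0.998 without the second, 0.573 without the first knockout array and 0.637 without the second. Averaging both Erdr1 probe sets gave -1.66 with an adjusted p of 0.203 in limma.

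**Figure D1:**
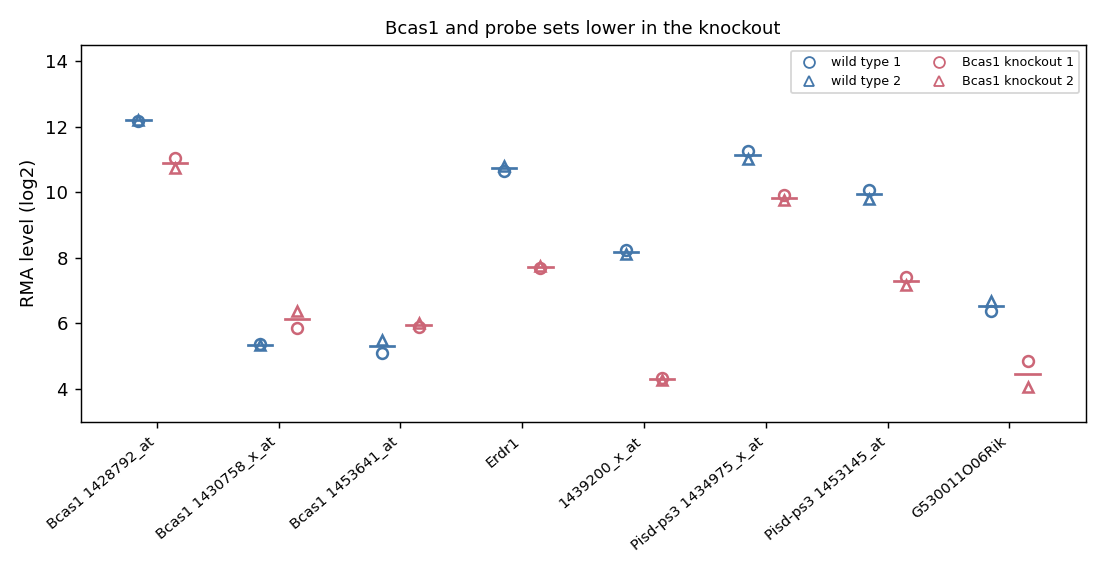
RMA log2 level (vertical axis) of the 3 Bcas1 probe sets, Erdr1, the unnamed probe set, 2 probe sets of Pisd-ps3 and G530011O06Rik in each array; circles are mice numbered 1, triangles mice numbered 2, and bars are means of 2 mice. Both knockout arrays lie below both wild-type arrays for every feature except the 2 dim Bcas1 probe sets, where they lie above.

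Beyond these features, 20 probe sets were at least 2-fold apart with the genotypes not overlapping, 13 lower and 7 higher in the knockout, Erdr1, the unnamed probe set and Bcas1 included. Chance alone leaves 33.3% of probe sets with no overlap between 2 groups of 2. Of the 13 lower, 8 named Pisd-ps3, alone or with its relatives; it is a pseudogene related to phosphatidylserine decarboxylase. The brightest Pisd-ps3 probe set measured 11.13 ± 0.17 in wild type and 9.84 ± 0.12 in the knockout (SD, n = 2 each), a difference of -1.30 (SE 0.12) with an adjusted p of 0.742 in limma. The 5 probe sets that named Pisd-ps3 alone gave differences from -2.65 to -0.95. The one at -0.95 is under 2-fold and not among the 8, of which 4 named Pisd-ps3 alone and 4 named several genes of this family and cannot be assigned to 1 of them. The dim probe set of G530011O06Rik, chosen after its values were seen, measured 6.53 ± 0.21 in wild type and 4.45 ± 0.56 in the knockout (SD, n = 2 each). The 7 higher probe sets were 3 of Gh, which encodes growth hormone, and 1 each of S100a8, S100a9, Obp2a and Bpifb3, the last 2 chosen after their values were seen and far apart from the other arrays only in the second knockout array.

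At the 1.5-fold limit 19 probe sets were higher and 23 lower in the knockout, 42 together. Splitting the same 4 arrays by mouse number gave 156 such probe sets, of which 128 were lower in the mice numbered 2, and the crossed split gave 15. By limma these splits gave 0 calls each at the adjusted threshold. At the 2-fold limit the genotype split gave 20, the split by mouse number 17, of which 16 were higher in the mice numbered 2, and the crossed split 2. Among probe sets above the median level the counts in the same order were 9, 0 and 0 at 2-fold and 20, 64 and 3 at 1.5-fold.

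Among genes above the median level with the genotypes not overlapping, the ranking by p named 12 genes higher in the knockout, and each had an adjusted p of 1 in limma. The differences ran from 0.27 (Hspb3) to 0.64 (Dnaic1). Dnaic1, a dynein component of motile cilia, measured 6.33 ± 0.18 in wild type and 6.97 ± 0.0071 in the knockout (SD, n = 2 each). Chac1, which degrades glutathione, was 0.62 higher (SE 0.12), and Slc7a3, a cationic amino acid transporter, was 0.36 higher (SE 0.081). Igf2, a growth factor, was 0.34 higher (SE 0.076), and Fmod, an extracellular matrix proteoglycan, was 0.41 higher (SE 0.097). Bex4, Rgs7, Cndp2, Steap1, Tipin and Ccnq made up the rest, at 0.28 to 0.44. On the lower side Erdr1, Pisd-ps3 and Bcas1 were followed by Per2, a circadian clock gene, at -0.42 (SE 0.091). Nt5c, Tha1, Dpyd, Vwa5b2, Nucb2, Zfp612, Fam71e1 and Cyp11a1 followed at -0.31 to -0.24, also with an adjusted p of 1 in limma.

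Several genes known from nasal tissue had high levels in the second knockout array alone, and the genes named here were chosen after their values were seen. In it Obp1a, an odorant-binding protein of nasal glands, measured 8.92, against 3.41 and 4.15 in wild type and 3.46 in the first knockout array. Bpifa1, a secreted protein of the airway lining, measured 8.33, against 3.91, 4.32 and 3.94. Cyp2g1, a cytochrome of the olfactory mucosa, measured 7.12, against 4.88, 4.99 and 4.65. The 10 nasal gland and epithelium genes picked in this way had a median deviation of 1.98 from the mean of the other 3 arrays, a size set by that choice. A list of 11 nasal mucosa genes not looked at before had a median deviation of 0.40. Gh, made in the pituitary, measured 6.44 and 6.55 in wild type and 6.88 and 7.53 in the knockout, a difference of 0.71 (SE 0.22) with an adjusted p of 1 in limma. The 3 dimmer Gh probe sets differed by 1.78 (SE 0.72), 1.66 (SE 0.65) and 2.01 (SE 0.67), each with an adjusted p of 1 in limma. Most of that lay in the second knockout array, where they measured 7.03, 6.37 and 6.71, against 4.82, 4.45 and 4.71 in the first.

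**Figure D2:**
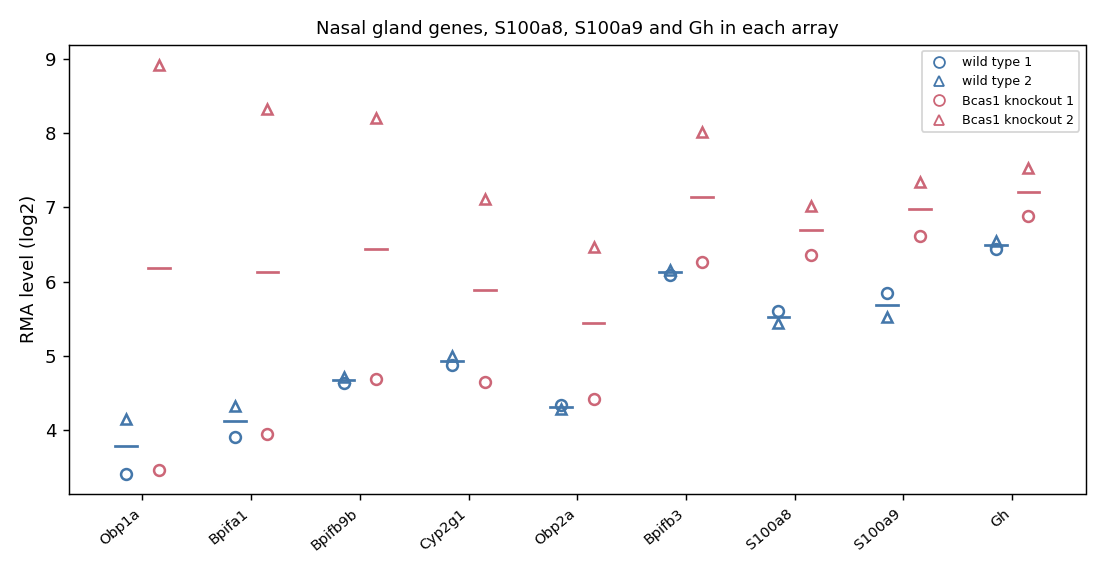
RMA log2 level (vertical axis) of 6 genes of nasal glands and epithelium, of S100a8 and S100a9, and of Gh in each array; circles are mice numbered 1, triangles mice numbered 2, and bars are means of 2 mice. The nasal genes stand apart in the second knockout array alone, at 8.92 for Obp1a, while S100a8, S100a9 and Gh are higher in both knockout arrays.

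Genes of mature oligodendrocytes were slightly higher in the knockout as a group, and genes of the myelin sheath did not pass the test. Of 27 measured genes of the mature oligodendrocyte list, 25 had positive differences and 0 passed alone, over all genes or when adjusted over the list alone. The median difference was 0.075. The list was shifted up relative to other genes with a camera adjusted p of 5.8e-04 in limma (adjusted p = 0.67 with an estimated correlation and 0.43 by fry). The camera p at the preset correlation compares genes with genes and does not measure the spread between mice. Myrf, the transcription factor that drives myelin genes, differed by 0.28 (SE 0.081), Tmem125 by 0.20 (SE 0.072), Ndrg1 by 0.18 (SE 0.078) and Olig1 by 0.16 (SE 0.078). Without the first knockout array the list had an adjusted p of 0.12. The myelin components list had a median of 0.040 over 18 measured genes, 16 of them positive, with an adjusted p of 0.11. It was 0.044 without the second knockout array, and 0.96 without the first, where the direction was down. Mbp, the main cytoplasmic myelin protein, differed by -0.055 (SE 0.081), Mog by 0.015 (SE 0.12) and Mag by 0.065 (SE 0.087), all within the spread between mice. Ermn, Gjb1, Mal and Omg had the largest differences of the list, 0.10 to 0.16.

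Lists of earlier stages of the lineage were not called by the same test. Newly formed oligodendrocyte genes had a median of 0.018 (14 measured, adjusted p 0.97), with Enpp6 at -0.090 (SE 0.11) and Lims2 at 0.15 (SE 0.088). Oligodendrocyte precursor genes had a median of -0.035 and a mean of 0.0072 (16 measured, adjusted p 0.97, camera direction down), with Pdgfra at 0.16 (SE 0.093) and Cacng4 at 0.16 (SE 0.068). Genes of cholesterol synthesis, a main lipid of myelin, had a median of 0.040 with 16 of 19 positive, and the list was called by camera (adjusted p = 0.047; adjusted p = 0.67 with an estimated correlation). Mvd differed by 0.25 (SE 0.084), Insig1 by 0.19 (SE 0.10) and Fdft1 by 0.14 (SE 0.085), and 0 of the 19 passed alone. The adjusted p of this list was 0.50 without the first knockout array, 0.41 without the second wild-type array and 0.058 without the second knockout array.

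Inflammatory, microglial and reactive astrocyte lists were not called by camera, and 0 of their members passed alone over all genes or adjusted over each list alone. With 2 mice per group this does not show that these genes were unchanged. Inflammatory mediators had a median difference of 0.022 (26 measured, 15 positive, camera adjusted p 0.93). Within them the cytokines Il1a and Tnf were 0.33 (SE 0.086) and 0.22 (SE 0.072) higher from dim levels, and Nos2 and Tlr4 were at -0.25 (SE 0.16) and -0.21 (SE 0.16). Many other mediators were dim as well, such as Il6 and Il1b at mean levels of 3.09 and 5.18, though some, such as Nfkbia at 11.63, were bright. Changes of dim genes are compressed, so the list test says little about them. Homeostatic microglia genes had a median of 0.0050 (21 measured, adjusted p 0.93), with the camera direction down, and activated microglia genes 0.020 (15 measured, adjusted p 0.45). Trem2 differed by 0.19 (SE 0.097), Cx3cr1 by -0.12 (SE 0.077), Ccl6 by -0.28 (SE 0.16) and Lgals3 by 0.25 (SE 0.11). Aif1, the microglial marker IBA1, measured 7.45 in both groups, with SDs of 0.042 and 0.057. Interferon response genes had a median of 0.022 (22 measured, adjusted p 0.93), with Oasl2 at -0.44 (SE 0.16) and Ifit2 at 0.21 (SE 0.080). Antigen presentation genes centred on 0 with a mean of -0.012 (14 measured, adjusted p 0.69), with Tap1 at -0.24 (SE 0.082) and Psmb8 at -0.11 (SE 0.076).

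Gfap, the intermediate filament of astrocytes, measured 8.71 ± 0.092 in wild type and 8.99 ± 0.028 in the knockout (SD, n = 2 each). The difference was 0.29 (SE 0.081) with an adjusted p of 1 in limma, and its 2 other probe sets differed by 0.095 and 0.17. The complement and reactive astrocyte list had a median of 0.015 and a mean of -0.0056 (18 measured, adjusted p 0.97, direction down), and Tgm1, Hspb1 and Cd44 were at -0.24, -0.15 and -0.14. Its complement genes, C3 and C4b, were not measured, so this list did not test complement. The astrocyte list had a median of -0.010 and a mean of 0.013 (14 measured, adjusted p 0.97, direction up), with Sox9 at 0.18 (SE 0.079) and Aqp4 at 0.085 (SE 0.090).

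S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, were higher in both knockout arrays. S100a8 measured 5.52 ± 0.11 in wild type and 6.69 ± 0.47 in the knockout (SD, n = 2 each), a difference of 1.17 (SE 0.23), and S100a9 differed by 1.30 (SE 0.27). The adjusted p of both was 1 over all genes, and both passed when adjusted over the list alone (adjusted p 0.016 for the lower). The other neutrophil genes of the blood cell list, Ngp and Camp, differed by 0.50 (SE 0.21) and 0.23 (SE 0.074), and the erythroid genes Alas2 and Hba-a1, chosen after their values were seen, by 0.075 (SE 0.19) and 0.010 (SE 0.19). The Hba-a1 probe set was dim, at 4.79 in both wild-type mice, and Hbb-b1, Hbb-bs and Hbb-bt were not measured. Bright globin probe sets named several genes and were outside the list. Their median difference from the wild-type mean was -0.14 in the first knockout array and 0.32 in the second. The list of 6 measured genes was called by camera (adjusted p 5.8e-04; adjusted p = 0.67 with an estimated correlation). Its adjusted p was 0.14 without the second knockout array, which also held the nasal transcripts, and 0.065 without the second wild-type array.

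Vascular and choroid plexus genes were also slightly higher as groups, again with 0 members past the threshold alone. The vascular list had a median of 0.070 with 13 of 14 positive and a camera adjusted p of 0.0065 (adjusted p = 0.67 with an estimated correlation). Tagln and Acta2, of smooth muscle, differed by 0.32 (SE 0.089) and 0.24 (SE 0.071), Pdgfrb, of pericytes, by 0.28 (SE 0.15), and Abcb1a, of endothelium, by 0.17 (SE 0.10). Without either knockout array the call was lost, with adjusted p of 0.069 without the first and 0.072 without the second. The choroid plexus list had a median of 0.080 with 12 of 16 positive and a camera adjusted p of 0.020 (adjusted p = 0.67 with an estimated correlation). Igf2, Sostdc1 and Igfbp2 were 0.34, 0.25 and 0.18 higher, and Tmem72 was 0.17 higher. The list mean was 8.03 and 8.09 in the wild-type mice and 8.05 and 8.23 in the knockout mice, so the first knockout array lay between the wild types. That list had an adjusted p of 0.71 without the second knockout array, which also held the nasal transcripts, and 0.19 without the first wild-type array.

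Activity-induced genes, which neurons switch on within minutes of firing, were lower in the knockout as a group. The median difference was -0.12 with 15 of 18 negative and 0 past the threshold alone, and the camera adjusted p was 0.0024 (adjusted p = 0.67 with an estimated correlation). Dusp1 differed by -0.28 (SE 0.16), Fos by -0.25 (SE 0.12), Npas4 by -0.24 (SE 0.22) and Arc by -0.22 (SE 0.075). The list mean was 9.97 and 9.84 in the wild-type mice and 9.83 and 9.77 in the knockout mice. Its adjusted p was 0.42 without the second knockout array and 0.31 without the first wild-type array. Heat shock genes had a median of -0.075, with Hspa1b, Dnajb1 and Hspa1a at -0.34, -0.24 and -0.22 and Hspa5 at -0.20. That list was called by camera (10 measured, adjusted p 0.026; adjusted p = 0.67 with an estimated correlation), and leaving out any array ended the call, at an adjusted p of 0.072 to 0.27.

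Neuronal lists were not called. Genes of glutamatergic neurons and synapses had a median of -0.0025 and a mean of 0.0063 (16 measured, camera adjusted p 0.92, direction down), with Neurod6 at -0.17 (SE 0.077) and Grin2a at 0.24 (SE 0.16). Genes of GABAergic neurons had a median of -0.0050 (15 measured, adjusted p 0.57), with Pvalb at -0.16 (SE 0.079) and Vip at -0.10 (SE 0.081). Among lists of brain regions, cerebellum genes were lower with a median of -0.038 and a camera adjusted p of 0.035 (12 measured; adjusted p = 0.67 with an estimated correlation). Zic1 and Gabra6 were each at -0.16 (SE 0.069 and 0.073), and Neurod1 and Cbln3 at -0.095. Leaving out the second wild-type array kept that call and leaving out any other array ended it, with an adjusted p of 0.26 without the first wild-type array, 0.069 without the first knockout array and 0.22 without the second. Striatum genes had a median of 0.048 (12 measured, adjusted p 0.093), with Gpr6 at 0.17 and Drd2 at 0.14, and thalamus genes -0.010 with a mean of -0.065 (11 measured, adjusted p 0.093), with Tnnt1 at -0.29 and Prkcd at -0.21. The hypothalamus and pituitary list had a median of 0.018 (12 measured, adjusted p 0.43), and 0.037 as its adjusted p without the first knockout array. Besides Gh, Prl was at 0.25 (SE 0.17) and Avp at -0.14 (SE 0.16).

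**Figure D3:**
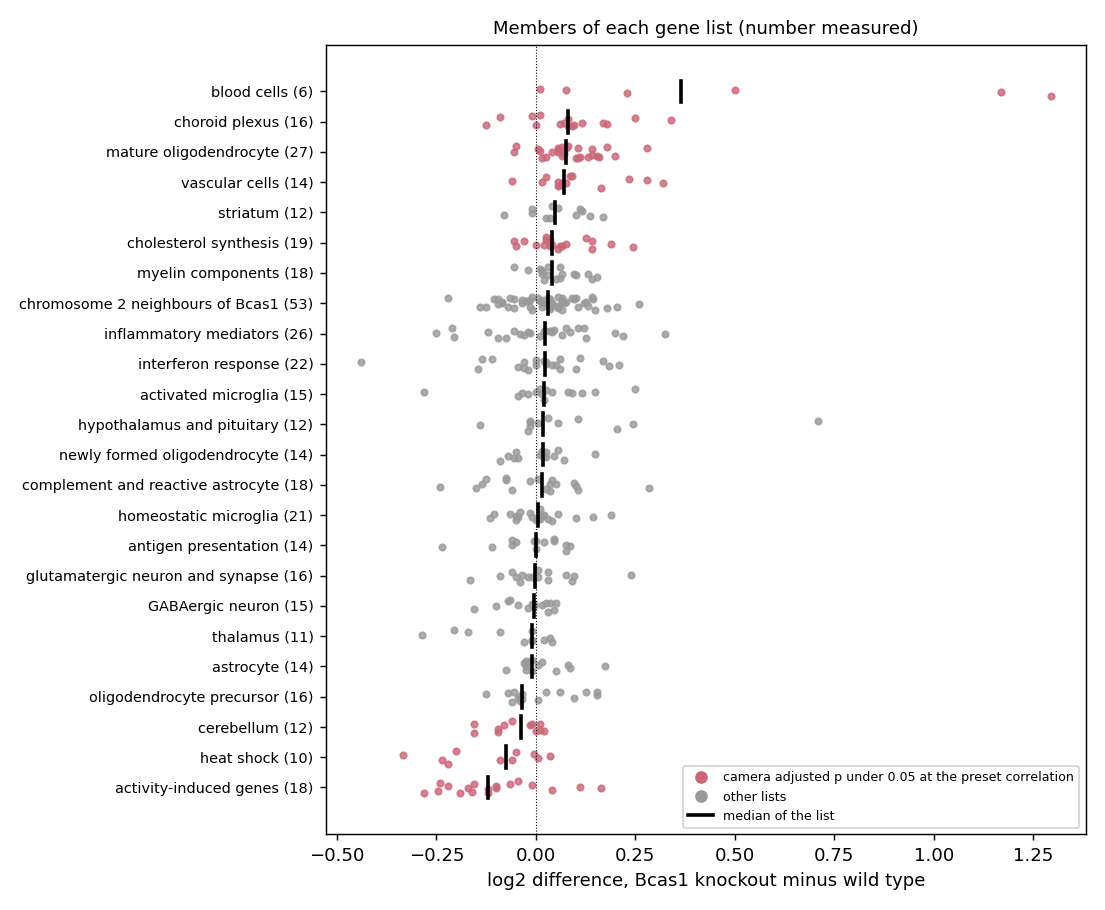
Difference of each member of the 24 gene lists, knockout minus wild type on the log2 scale (horizontal axis), 1 point per gene, with the number measured in brackets and a black bar at the list's median; red points mark lists with a camera adjusted p under 0.05 at the preset correlation. The medians run from -0.12 for activity-induced genes to 0.37 for blood cells, and 8 of the 24 lists are red. None of these kept its call with an estimated correlation, where camera uses the 2 residual degrees of freedom, or by fry.

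Genes next to Bcas1 on chromosome 2 were listed because a targeted allele can carry flanking sequence of another strain. Of 53 measured neighbours, 0 passed the threshold, and the median difference was 0.030 (camera adjusted p 0.69). Rbm38, Kcng1, Snai1 and Dpm1 had the largest differences, 0.26 (SE 0.11), -0.22 (SE 0.080), 0.21 (SE 0.084) and 0.18 (SE 0.097). Only 2 of 45037 probe sets passed at all, and Bcas1 itself at -1.29 did not. The absence of calls among its neighbours therefore does not count against flanking sequence. Across all 24 lists, 0 of 419 measured entries passed over all genes, where limma with all probe sets set the adjustment.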

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

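Array weights were chosen after the data were seen, and all other settings before the data were examined. Median-centred arrays left every call and direction tested here as it was. The cause of the shifts given here was not tested, except that leaving out an array removes 1 of 2 residual degrees of freedom and averaging mixes bright with dim probe sets. An estimated correlation also makes camera draw its p from the 2 residual degrees of freedom. With 1 array left in a group, that array is assumed to vary like the other group. In 2 against 2, array weights came out equal within each group, 1.41 for wild type and 0.709 for the knockout, and so could not single out the second knockout array.

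With the intensity trend and robust variance, 10 probe sets and 3 genes were lower, the genes being Bcas1 (-1.29, adjusted p 0.0383 in limma), Erdr1 and Pisd-ps3. Lists for myelin components (0.0393), striatum (0.0393) and thalamus (0.0437) then passed, and the astrocyte list turned direction at 0.988; these and the following list values are adjusted p. The filter on dim probe sets left 1 probe set lower, kept 7 of the 8 list calls and brought in myelin components (0.0471) and striatum (0.0394); the blood cell list, with 1 of its 6 measured genes left, could not be tested, so 23 lists were. It turned oligodendrocyte precursor, inflammatory mediators and antigen presentation (each 0.887) and reactive astrocyte (0.742). Repeated quantile normalization turned oligodendrocyte precursor (0.982). Averaging probe sets left 0 genes lower, with thalamus at 0.00718, cholesterol synthesis at 0.0664, cerebellum at 0.0918 and vascular cells at 0.0758. It turned antigen presentation (0.176) and astrocyte (0.954), and the differences of Enpp6 (0.01), Nkd1 (0.065) and Sox5 (-0.0014). Array weights put cholesterol synthesis at 0.0509.

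With an estimated correlation the 8 lists called were each at 0.666. The correlation itself was below the preset 0.01 for mature oligodendrocyte (-0.0035), cholesterol synthesis (-0.011) and cerebellum (-0.063). A higher correlation therefore did not end the calls of these lists. By fry the same 8 were at 0.432 (mature oligodendrocyte and cerebellum), 0.523 (cholesterol synthesis), 0.522 (vascular cells), 0.690 (activity-induced, blood and heat shock) and 0.825 (choroid plexus). Fry turned oligodendrocyte precursor and reactive astrocyte (both 0.927) and homeostatic microglia (0.941). Of probe sets at least 1.5-fold apart, the 2-fold limit left 7 higher and 13 lower, and the dim filter 6 higher and 14 lower.

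Nothing in the labels ties mice of equal number together, and with 2 pairs the correlation of their deviations (0.241) does not settle whether the numbers pair them. With the number as a replicate block, 0 probe sets and 0 genes were lower, with Erdr1 still at -3.01 (adjusted p 0.847 in limma), the same 8 lists were called, and newly formed oligodendrocyte turned (0.937).

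Leaving out each array in turn gave 0 to 0 lower probe sets and 0 to 0 lower genes. Bcas1 stayed between -1.44 and -1.14. The adjusted p of called lists ran from 6.4e-04 to 0.117 (mature oligodendrocyte), 0.0244 to 0.504 (cholesterol synthesis), 6.5e-06 to 0.418 (activity-induced), 0.0315 to 0.262 (cerebellum), 0.00548 to 0.712 (choroid plexus), 0.0315 to 0.0724 (vascular cells), 8.0e-04 to 0.141 (blood cells) and 0.0724 to 0.272 (heat shock). Lists that turned direction in at least 1 case ran from 0.0444 to 0.962 (myelin components), 0.750 to 0.962 (newly formed oligodendrocyte), 0.199 to 0.987 (oligodendrocyte precursor), 0.380 to 0.953 (inflammatory mediators), 0.794 to 0.998 (homeostatic microglia), 0.110 to 0.962 (interferon response), 0.748 to 0.931 (reactive astrocyte), 0.111 to 0.931 (astrocyte), 0.0520 to 0.989 (glutamatergic neuron) and 0.0372 to 0.953 (hypothalamus and pituitary). Named genes that turned were Ermn (-0.03 to 0.34), Gjb6 (-0.025 to 0.19), Hspa1a (-0.47 to 0.025), Tlr4 (-0.43 to 0.005), Hspb1 (-0.43 to 0.13), Aqp4 (-0.005 to 0.18), Grin2b (-0.025 to 0.22), Gria3 (-0.17 to 0.35), Npy (-0.22 to 0.075), Avp (-0.36 to 0.08), Hspa5 (-0.42 to 0.02), Mog (-0.14 to 0.17), Enpp6 (-0.21 to 0.025), Rlbp1 (-0.28 to 0.03), Tap2 (-0.04 to 0.21), Npas4 (-0.50 to 0.015), Pdyn (-0.005 to 0.24) and Mbp (-0.12 to 0.01).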

Other observations

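Most probe sets of the long noncoding RNAs Malat1, Meg3 and Snhg11 were lower in the mice numbered 2 than in those numbered 1, in both genotypes. The split by mouse number gave 0 calls at the adjusted threshold in limma, and long noncoding RNAs were not tested as a group. Malat1 was lower in both arrays numbered 2 for 6 of 7 probe sets, with a median difference of -0.25, and Meg3 for 10 of 11, with a median of -0.32. Snhg11 was lower for 2 of 2, with a median of -0.375. Rian went both ways, lower for 2 of 4 with a median of -0.09, while its brightest probe set was 0.37 higher in the mice numbered 2. Of the 128 probe sets at least 1.5-fold lower in the mice numbered 2, 74.2% had no gene name here, against 20.3% of all tested (Fisher's exact test, two-sided p = 3.7e-39, over probe sets, which are not independent). Snhg11, Rian, Malat1 and Meg3 were chosen after their values were seen.

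Tests of array-wide noise, unplaced genes, repeated sequence, blood and neutrophil genes were chosen or tightened after results had been seen; those of noise and blood replaced earlier tests whose results are given with them. In the second knockout array 10 nasal gland genes, picked for it, stood apart, with Obp1a at 5.25 and Bpifa1 at 4.27 above the mean of the other 3 arrays. An earlier test of array-wide noise came out on the side of noise. To count against it, most 2-fold deviations had to go in the same direction, and 32 were higher and 21 lower (60.4%). In its replacement, 11 nasal mucosa genes not looked at before had a median deviation of 0.40, above all 10000 matched random lists. That argues against noise for these genes, but the same value serves the mucosa test that follows and is not separate evidence. Olfactory mucosa in the sampled tissue may account for the pattern: the nasal mucosa list and 6 olfactory sensory neuron genes (median 0.38) both lay at percentile 100. A larger share of olfactory bulb stays open as well, with 10 bulb genes at percentile 100 but a median of only 0.20, and neither source excludes the other. In the first knockout array the 10 picked genes were near wild-type level, with a median of -0.028 against the wild-type mean (percentile 43.1). The other lists were lower there: nasal mucosa at -0.105 (percentile 7.2), sensory neuron at -0.14 (2.4) and bulb at -0.098 (2.7). Low values in that array enlarge the deviation of the second from the other 3. The bulb list mean was 7.94 in the second knockout array and 7.74 in the first, against 7.865 and 7.88 in wild type. No biological explanation by genotype was tested.

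The 13 probe sets at least 2-fold lower in both knockout arrays are mostly of Pisd-ps3 and its relatives, with Erdr1, G530011O06Rik and Bcas1 among the others. For a chromosome 2 segment of another strain linked to Bcas1, 0 of the 2 placed genes, Erdr1 and G530011O06Rik, lie on chromosome 2. Both lie on X in GRCm38.p6, which argues against the segment only where a probe set reads the gene it names. For Erdr1 this cannot decide. Its called probe set carries a suffix for probes shared between transcripts, and its other, dim probe set differed by -0.31 with the genotypes overlapping. The unnamed probe set, which fell most, could not be placed. For the 1 gene on unplaced sequence, Pisd-ps3, the segment and another cause cannot be told apart, because its chromosome is not given. Whether 1 repeated sequence was read by several probe sets also stays open: 69.2% of the 13 carry a suffix for probes shared between transcripts, against 19.9% of all, but the family was known before that test, 3 of the 9 with the suffix name no gene of it, and probe sequences were not used here. An effect of losing Bcas1 on these transcripts, and a difference in copy number between the mice, remain untested.

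S100a8 and S100a9 were higher in both knockout arrays, and more blood left in the tissue is argued against for the first knockout array, where S100a8 was 0.84 above the wild-type mean while 4 bright globin probe sets had a median of -0.14 and 0 of them lay above both wild-type arrays. For the second it stays open, since all 4 lay above both wild-type arrays (median 0.32), with S100a8 at 7.02 against a wild-type mean of 5.52; earlier tests on 4 erythroid genes (median 0.048) and on globin in the first arrays of each group alone (-0.28) came before these. Whether neutrophil RNA contributed stays open: 12 other neutrophil genes had a median difference of 0.10, at percentile 97.7 of matched random lists, just past the limit first set, but 3 of them were members of the fixed lists, Ngp (0.50) and Camp (0.23) included, and the 9 others had a median of 0.095, at percentile 93.9. That shift rests on the second knockout array (median 0.21), and in the first the list lay at percentile 44.6, so neutrophils there cannot be told apart from another source with 12 mostly dim genes. Inflammatory gene expression in the knockout brain also stays open, with an adjusted camera p of 0.93 for the mediator list.

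Pituitary genes other than Gh, 8 measured, had a median deviation of 0.17 in the second knockout array, at percentile 94.8 of matched random lists, and the 5 of them outside the fixed lists had a median of 0.020, at percentile 22.1.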
